A study of Mus musculus with 18 samples.

How the data were processed

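RNA of sorted GFP-positive and GFP-negative cells from days 5 to 8 of differentiation (2 batches) and of G418-selected cardiomyocytes (2 arrays) was measured on Affymetrix mouse arrays. Per the labels, RNA went through 2 rounds of amplification with a T7 oligo dT primer before labelling. The deposited values are MAS5 signal intensity on a linear scale, made by the authors with GCOS 1.4 and MAS5. The trimmed mean of each array, with 2% of probe sets left out at each end, ranged from 150.0008 to 150.0012 over the 18 arrays. No detection calls or image files were in the deposit, so background could be judged only from the signal, whose highest value was 13341.1.

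Groups, batches and replicate numbers came from the sample titles. The batch number was taken to pair the 2 fractions of a day and the days of a fraction. Correlations of batch differences across genes between 28 pairs of groups ranged from -0.184 to 0.655, and 13 were over 0.1. The comparisons, the 16 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated.

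Of 45101 probe sets, 64 were controls, 9211 had no gene symbol and 932 had several, and these were left out. Symbols were checked through Entrez identifiers for 34754 probe sets, which changed 0 symbols. For each of 18193 genes the probe set with the highest mean was used, with probe sets of type x taken only where no other existed. Genes with a signal of at least 22.5, the median of all values, on at least 2 arrays were tested, which left 13359. Signals were used as log2(signal + 6.8), where the offset is the 25th percentile.

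Group means were fitted with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, 9 residual degrees of freedom and Benjamini-Hochberg adjustment over the genes of a comparison. The threshold was an adjusted p of 0.05. The comparisons were GFP-positive against GFP-negative over all days and on each day, day 8 against day 5 in each fraction, the interaction of these, and selected cardiomyocytes against day 8 GFP-positive cells. A fit with batch as a covariate had 8 residual degrees of freedom and gave the cardiomyocytes no batch. Where 1 array of a group was left out, the lone array was assumed to vary like the other groups.

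Gene lists were tested with camera, a competitive test in limma, at a preset correlation between genes of 0.01, and the p-values were adjusted over 144 pairs of list and comparison. The lists held 303 members, of which 301 were distinct genes, 261 memberships were tested and 13 had no probe set of their own. Camera was repeated with the correlation estimated from the data. A count adjusted over the list alone used the same gene p-values, adjusted within the list.

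Genes were named by rule: the 10 highest and 10 lowest past the threshold with the same sign in every pair (5 and 5 on single days), with clone and model names passed over, up to 4 members of each list past the threshold or else the 2 with the lowest p, and Nkx2-5 and Myh6 always. The report names part of these.

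In simulated data 100 genes were changed by a log2 of 1 and another 100 by 2. At a log2 change of 1 the fit called 77% of them in the comparison over all days, between 27% and 29% on single days, 25% and 31% between days in GFP-positive and GFP-negative cells, 14% in the interaction and 37% for the cardiomyocytes. At a log2 change of 2 it called 98% over all days, 52% in the interaction and between 73% and 87% in the others. A sarcomere list raised by 1 on day 8 had adjusted p = 6.89e-04, and 0.0232 with an estimated correlation. Both were adjusted over 16 lists, not 144 pairs, so detection in real data stays open.

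Alternatives covered the offset, the scaling (quantile normalization and equal array medians), the filter on dim genes, the choice of probe sets, the variance trend, array weights, batch or pair as a block, the sorted arrays alone, a linear trend over the days, another reference for the cardiomyocytes and leaving out each array. Exact permutation tests exchanged signs over the pairs or arrays. Plots were made with Python 3.11.15 and matplotlib 3.10.9.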

Results

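The series followed mouse embryonic stem cells of the D3 line as they formed heart cells. One clone carried green fluorescent protein (GFP) under an enhancer of Nkx2-5, a homeobox transcription factor of early heart cells, joined to a minimal hsp68 promoter. It was differentiated as embryoid bodies, which are floating aggregates of differentiating cells, and sorted by flow cytometry into GFP-positive and GFP-negative cells on days 5, 6, 7 and 8. Another clone carried a neomycin resistance gene under the promoter of alpha myosin heavy chain (Myh6), and its cardiomyocytes were selected with the antibiotic G418. RNA was measured on 18 Affymetrix arrays of 45101 probe sets, in 9 groups of 2 arrays. Each sorted group had 1 array of batch 1 and 1 of batch 2, while the labels give the selected cardiomyocytes neither a day nor a batch. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

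Values are MAS5 signals, already scaled to a common trimmed mean. The median signal of an array lay between 18.2 and 29.3 units, and the number of arrays limits the precision. Arrays of the same group correlated across probe sets, which are not independent replicates, with r between 0.936 and 0.985. A cardiomyocyte array and a sorted array correlated with r between 0.767 and 0.844. The ratio of 3' to 5' Gapdh signal, a measure of RNA quality, lay between 1.13 and 1.64. Fold changes below are on the scale of log2(signal + 6.8), which understates changes of dim genes, and their errors are standard errors (SE) from a limma fit to all arrays. Each group has n = 2, and 13359 genes were tested.

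Nkx2-5 was higher in GFP-positive cells in 8 of 8 pairs of the same day and batch. Averaged over the days it rose by 1.07 ± 0.26 (log2, SE; 8 arrays against 8; adjusted p = 0.0438). The difference was 1.14 in batch 1 and 1.00 in batch 2. On day 8 its signal was 249.2 and 323.2 in GFP-positive cells against 76.3 and 79.4 in GFP-negative cells, and it was 474.4 and 500.0 in selected cardiomyocytes. Myh6 was higher in 7 of 8 pairs. Its difference of 1.81 ± 0.81 did not pass the threshold (adjusted p = 0.256, and 0.0382 with batch as a covariate), with 2.02 in batch 1 and 1.6 in batch 2. The batches differed most at the early days: the day 5 GFP-positive signal of Myh6 was 729.5 in batch 1 and 19.5 in batch 2, against 188.5 and 25.0 in GFP-negative cells. Each gene has 1 variance over all groups, so this gap widens the Myh6 SE throughout. The Nkx2-5 call was close to the threshold: its adjusted p was 0.658 without batch 1, and with single arrays left out it ranged from 0.0112 to 0.121 and missed the threshold in 12 of 16 fits.

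**Figure D1:**
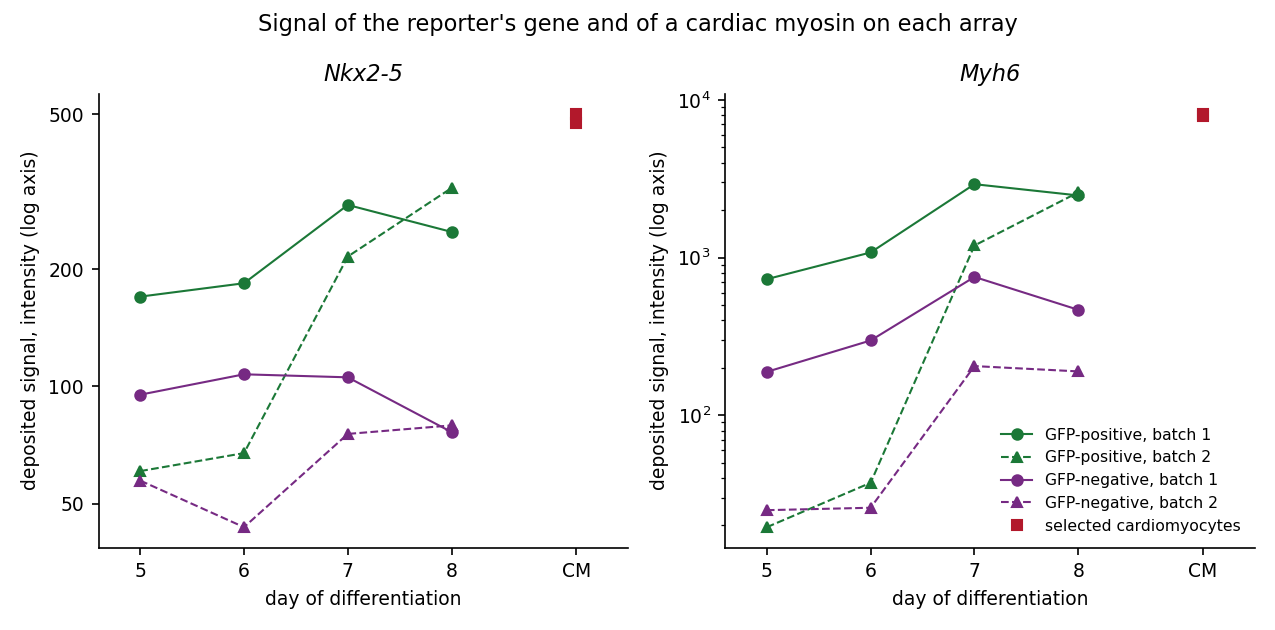
Signal of Nkx2-5 and Myh6 on each array (log axis, MAS5 signal units) by day of differentiation, sorted fraction and batch, with the 2 selected cardiomyocyte arrays as squares. Nkx2-5 was higher in GFP-positive cells in 8 of 8 pairs of the same day and batch, and Myh6 in 7 of 8.

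The comparison of GFP-positive with GFP-negative cells over all days asked which genes mark cells with an active Nkx2-5 enhancer. Of the genes with the same sign in 8 of 8 pairs, those with the largest increases were mainly known from blood vessels. Mmrn2, an extracellular matrix protein of endothelium, rose by 2.62 ± 0.58 (log2; adjusted p = 0.0313). Icam2, an adhesion molecule of endothelium, rose by 2.27 ± 0.44 (adjusted p = 0.0178), and Sox7, a transcription factor of early endothelium, by 2.07 ± 0.20 (adjusted p = 4.02e-04). Calcrl, a receptor subunit for adrenomedullin, rose by 2.17 and Plvap, a protein of endothelial pore diaphragms, by 1.94. Erg, an endothelial transcription factor, rose by 1.94, Ptprb, the phosphatase of endothelial junctions, by 1.93, and Pcdh12, an endothelial protocadherin, by 1.90. Dpp4, a cell surface peptidase, rose by 2.08 and Hapln1, a link protein of hyaluronan, by 2.07.

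Among genes lower in 8 of 8 pairs, the largest decreases included genes of undifferentiated cells. Utf1, a chromatin protein of pluripotent cells, fell by 1.58 ± 0.21 (log2; adjusted p = 0.00239), Zfp42, also known as Rex1, fell by 1.35 and Fbxo15, an F-box gene of stem cells, fell by 1.10. Cntnap2, a neuronal adhesion protein, fell by 1.48 ± 0.15 (adjusted p = 4.21e-04), Hesx1, a homeobox gene of the anterior neural plate, fell by 1.20 and the homeobox gene Hoxc10 fell by 1.42. Cthrc1, a secreted matrix protein, fell by 1.55, and Prss2, Rhox9 and Defa31 fell, at -1.49, -1.08 and -1.04.

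Endothelium gave the clearest list result. Of 20 endothelial genes tested, 12 rose, none fell and 8 did not pass, while 18 rose when adjusted over the list alone. The examples were Icam2, Plvap, Erg and Sox18, a transcription factor of vessels, which rose by 1.83 ± 0.30. The list median was 1.43 (log2; 1.52 in batch 1 and 1.31 in batch 2), and the list passed the test (adjusted p = 6.84e-19), but adjusted p = 0.350 with an estimated correlation. Of 18 endoderm genes, 3 rose and 15 did not pass, with 11 higher and 1 lower when adjusted over the list alone and 9 higher with batch as a covariate. Apob, a carrier protein of lipoproteins, rose by 2.17 ± 0.47, Apoc2, an activator of lipoprotein lipase, by 1.29 ± 0.23 and Hnf4a, a transcription factor of visceral endoderm and liver, by 1.10 ± 0.24. The endoderm median was 1.06 (1.27 and 0.82 within the batches; adjusted p = 5.23e-06, but adjusted p = 0.350 with an estimated correlation).

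Genes of heart muscle were higher as a group beside these endothelial and endodermal genes, with few single genes past the threshold. All 23 sarcomere genes had positive differences and 0 passed in limma, while 2 passed when adjusted over the list alone and 8 with batch as a covariate. Myl7, the atrial myosin light chain, differed by 1.35 ± 0.36 (adjusted p = 0.0659, and 0.00448 with batch as a covariate), and Actn2, the alpha-actinin of Z-discs, by 1.41 ± 0.38 (adjusted p = 0.0698, and 0.00640 with batch). The sarcomere median was 1.29 (1.29 and 1.13 within the batches; adjusted p = 2.47e-07, but adjusted p = 0.505 with an estimated correlation). Of 17 genes of calcium handling and ion channels, 1 rose, Slc8a1, the sodium-calcium exchanger of heart muscle, by 1.47 ± 0.28, and 16 did not pass. When adjusted over the list alone 6 rose, and 3 rose with batch as a covariate. Its median was 0.52 (0.57 and 0.29 within the batches; adjusted p = 2.92e-04, but adjusted p = 0.350 with an estimated correlation). Of 19 cardiac transcription factors, Nkx2-5 alone rose, with 4 when adjusted over the list alone and 5 with batch as a covariate. The median was 0.41 (0.32 and 0.57 within the batches; adjusted p = 0.00149, but adjusted p = 0.533 with an estimated correlation).

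Of 19 cardiac signalling genes, Notch1, a receptor used in vessels and heart, rose by 1.51 ± 0.17 and its target Hey1 by 0.90 ± 0.21, while Sfrp1, a secreted WNT inhibitor, fell by 0.90 ± 0.21. The other 16 did not pass, and 4 rose and 1 fell when adjusted over the list alone. The median was 0.19 (0.02 and 0.38 within the batches; adjusted p = 0.0299, but adjusted p = 0.505 with an estimated correlation). Of 19 pluripotency genes, 1 rose, 5 fell and 13 did not pass, with 2 higher and 10 lower when adjusted over the list alone and 8 lower with batch as a covariate. Nanog and Sox2, transcription factors of pluripotent cells, fell, at -1.82 ± 0.41 and -1.53 ± 0.30. The median was -0.52 (-0.51 and -0.62 within the batches; adjusted p = 0.00239, but adjusted p = 0.414 with an estimated correlation). Of 23 cell cycle genes, 2 fell, both small: Ccnb2, a mitotic cyclin, at -0.42 ± 0.09 and Birc5, survivin, at -0.32 ± 0.08. The same count fell when adjusted over the list alone, and the median was -0.16 in both the list and batch 2 and -0.15 in batch 1 (adjusted p = 0.00130, but adjusted p = 0.650 with an estimated correlation).

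The remaining lists did not pass the list test over all days. Of 16 genes of the primitive streak and early mesoderm, Kdr, the VEGF receptor of vascular progenitors, rose by 1.42 ± 0.22 and Cited1, a transcriptional coregulator, by 1.12 ± 0.24, the same 2 when adjusted over the list alone (list adjusted p = 0.699). Smtn, smoothelin of contractile smooth muscle, rose by 0.75 ± 0.13 as 1 of 10 smooth muscle genes (list adjusted p = 0.0891). Atf3, a stress-response transcription factor, rose by 0.61 ± 0.12 as 1 of 14 genes of dissociation stress (list adjusted p = 0.199). Otx2, a transcription factor of the epiblast and forebrain, fell by 1.72 ± 0.33 as 1 of 10 neuroectoderm genes, with 2 lower when adjusted over the list alone (list adjusted p = 0.155). In limma 0 of 16 blood genes passed, with Ptprc, the leukocyte antigen CD45, at -0.62 (list adjusted p = 0.620). Another 0 of 17 fibroblast and matrix genes passed, with Sparc at 0.67 (adjusted p = 0.188, and 0.0361 with batch as a covariate) and Lum at -1.54 (adjusted p = 0.103, and 0.00818 with batch). The fibroblast list had a median of -0.37 (-0.77 and -0.01 within the batches), with adjusted p = 0.116, and 0.0265 with batch as a covariate, but with batch adjusted p = 0.551 with an estimated correlation. The counts were also 0 of 16 for natriuretic peptides and muscle energy metabolism, with Mb, myoglobin, at 0.81 (list adjusted p = 0.138), and 0 of 4 for skeletal muscle, with Acta1 at 0.93 (adjusted p = 0.235, and 0.0485 with batch; list adjusted p = 0.705).

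In all, 359 genes differed between the fractions, 287 higher and 72 lower in GFP-positive cells, and 174 of these by at least 2-fold (152 higher and 22 lower). With batch as a covariate the count was 728 (534 higher and 194 lower). Batch 2 alone gave 0 calls in limma against 953 genes at an unadjusted p under 0.05, and batch 1 alone gave 478. The count fell to 129 without the day 7 GFP-positive array of batch 1, 133 without day 8 GFP-positive batch 2, 164 without day 6 or day 8 GFP-positive batch 1, 187 without day 7 GFP-negative batch 2, 194 without day 6 GFP-negative batch 1 and 223 without day 8 GFP-negative batch 2, and it was 583 without day 8 GFP-negative batch 1. Sox7, Ptprb, Pcdh12, Utf1, Cntnap2 and Notch1 passed in each of the 16 fits that left out 1 array.

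Single days were compared to see when the fractions parted. On day 5 pluripotency genes had the list median furthest from 0 and endothelial genes the lowest list p, and 2 genes passed: Utf1 fell by 3.26 ± 0.42 (log2; 2 arrays against 2; adjusted p = 0.0439) and Pim2, a serine/threonine kinase of proliferating cells, fell by 2.88 ± 0.40 (adjusted p = 0.0439). With batch as a covariate 4 genes passed, and the 2 added, named after their values were seen, were Cntnap2, at -1.99 (adjusted p = 0.0656, and 0.0110 with batch), and Sox2, at -3.46 (adjusted p = 0.104, and 0.00775 with batch). Of 19 pluripotency genes 1 fell, Utf1, with 9 lower when adjusted over the list alone. The median was -1.08 (-1.46 and -0.96 within the batches; adjusted p = 4.78e-09, but adjusted p = 0.350 with an estimated correlation). All 20 endothelial genes had positive differences and 0 passed in limma, with 2 higher when adjusted over the list alone and Flt4, a VEGF receptor, at 1.25. Their median was 0.94 (1.32 and 0.51 within the batches; adjusted p = 1.92e-09, but adjusted p = 0.350 with an estimated correlation). The gene count was 38 without the day 5 GFP-negative array of batch 1 and 24 without GFP-positive batch 1. It was 0 without either day 5 array of batch 2, with 402 genes at an unadjusted p under 0.05 without the GFP-negative array and 987 without the GFP-positive array, against 803 with all arrays.

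Further day 5 lists passed with 0 members called in limma. Blood genes had a median of 0.51 (0.57 and 0.65 within the batches), with 3 of 16 higher when adjusted over the list alone, among them Lmo2 and Tal1, transcription factors of early blood and endothelium, at 1.89 and 1.4 (list adjusted p = 2.92e-04, but adjusted p = 0.584 with an estimated correlation). Sarcomere genes had a median of 0.58 (1.08 and 0.19 within the batches; adjusted p = 0.0128, but adjusted p = 0.741 with an estimated correlation), with Myl7 at 1.15 ± 0.72. Cardiac transcription factors had a median of 0.43 (0.30 and 0.24 within the batches; adjusted p = 0.0125, but adjusted p = 0.623 with an estimated correlation), with Tbx20 at 0.80. Neuroectoderm genes had a median of -0.42 (-0.76 and -0.07 within the batches; adjusted p = 0.00613, but adjusted p = 0.350 with an estimated correlation), with Otx2 at -2.99 and Sox3 at -1.70, both lower when adjusted over the list alone. Calcium handling genes had a median of 0.25 (0.35 and 0.01 within the batches), with adjusted p = 0.0916, and 0.0459 with batch as a covariate, but with batch adjusted p = 0.409 with an estimated correlation. Nkx2-5 differed by 0.43 ± 0.51 and Myh6 by 0.82 ± 1.63, both with adjusted p = 0.997. The median of 18 endoderm genes was 0.40 in batch 1 and -0.52 in batch 2 (list adjusted p = 0.114).

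On day 6 limma called 0 genes, against 330 at an unadjusted p under 0.05. With batch as a covariate 1 gene passed, Cntnap2, named after its values were seen, at -2.08 (adjusted p = 0.123, and 0.0134 with batch), and 1 gene passed without the day 6 GFP-negative array of batch 1. All 20 endothelial genes again had positive differences, with Eng, an endothelial coreceptor for TGF-beta, at 0.75 ± 0.25. Their median was 1.00 (1.34 and 0.79 within the batches; adjusted p = 6.89e-14, but adjusted p = 0.350 with an estimated correlation). Sarcomere genes had a median of 0.75 (1.23 and 0.23 within the batches; adjusted p = 0.00269, but adjusted p = 0.709 with an estimated correlation), with Actn2 at 1.37 ± 0.76. Pluripotency genes had a median of -0.41 (-0.58 and -0.74 within the batches; adjusted p = 2.08e-04, but adjusted p = 0.350 with an estimated correlation), with Sox2 at -2.16 and Zfp42 at -1.68. Dissociation stress genes had a median of 0.08 (0.21 and 0.05 within the batches; adjusted p = 0.0335, but adjusted p = 0.541 with an estimated correlation), with Atf3 at 0.78. Neuroectoderm genes had a median of -0.33 (-0.24 and -0.83 within the batches; adjusted p = 0.0398, but 0.0622 with batch as a covariate and adjusted p = 0.350 with an estimated correlation). Otx2, at -3.41, was the 1 neuroectoderm gene that passed when adjusted over the list alone, and in the other 4 lists 0 did. Nkx2-5 differed by 0.65 ± 0.51 and Myh6 by 1.13 ± 1.63.

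On day 7 limma called 0 genes, against 1136 at an unadjusted p under 0.05. Of 18 endoderm genes 16 had positive differences and 6 were higher when adjusted over the list alone, with Apoc2 at 1.90 ± 0.46 and Amn, an endocytic receptor subunit, at 1.73 ± 0.50. Their median was 1.78 (1.97 and 1.47 within the batches; adjusted p = 1.74e-07, but adjusted p = 0.350 with an estimated correlation). The 20 endothelial genes were all positive and 6 were higher when adjusted over the list alone, with a median of 1.47 (1.53 and 1.39 within the batches; adjusted p = 9.84e-11, but adjusted p = 0.350 with an estimated correlation). Sarcomere genes had a median of 1.47 (1.44 and 1.54 within the batches; adjusted p = 6.28e-05, but adjusted p = 0.584 with an estimated correlation). Calcium handling genes had a median of 0.56 (0.77 and 0.36 within the batches; adjusted p = 2.92e-04, but adjusted p = 0.350 with an estimated correlation), with 2 higher when adjusted over the list alone, Slc8a1 at 2.23 and the calcium channel gene Cacna1c at 1.59. Cardiac transcription factors had a median of 0.48 (0.52 and 0.61 within the batches; adjusted p = 0.0105, but adjusted p = 0.623 with an estimated correlation), with Nkx2-5 at 1.42 ± 0.51 and Hopx at 1.32. Cardiac signalling genes had a median of 0.51 (0.21 and 0.57 within the batches; adjusted p = 0.0312, but adjusted p = 0.505 with an estimated correlation), with Notch1 at 1.75, the 1 gene that passed when adjusted over the list alone. Cell cycle genes had a median of -0.31 (-0.30 and -0.18 within the batches; adjusted p = 3.25e-05, but adjusted p = 0.545 with an estimated correlation). Myh6 differed by 2.22 ± 1.63.

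Day 8 showed the widest single-day difference, with endodermal and endothelial genes at its top. Igfbp1, a secreted binding protein of insulin-like growth factors, rose by 4.86 ± 1.05 (log2; 2 arrays against 2; adjusted p = 0.0328). Nepn, a proteoglycan gene of foregut endoderm, rose by 4.57 ± 1.05, Apob by 4.25 ± 0.94, Icam2 by 3.84 ± 0.88 and Tff3, a secreted trefoil peptide of mucosal epithelium, by 3.74 ± 0.61. The largest decreases, clone names passed over, were Hoxc10 at -2.99 ± 0.47 (adjusted p = 0.00966), Mbnl3, an RNA-binding protein, at -2.58, Wt1, a transcription factor of mesothelium and kidney, at -2.0, Brinp1 at -1.97 and Spata3 at -1.97. In all 347 genes passed, 312 higher and 35 lower, and 307 of them by at least 2-fold (293 higher and 14 lower). With batch as a covariate 704 passed (579 higher and 125 lower). The count depended on single arrays: it was 25 without the GFP-positive array of batch 1, 11 without the GFP-negative array of batch 2 and 715 without the GFP-negative array of batch 1. Without the GFP-positive array of batch 2 it was 0 in limma, with 1468 genes at an unadjusted p under 0.05. It was 178 under equal array medians.

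Of 18 endoderm genes at day 8, 5 rose and 13 did not pass, while 13 rose when adjusted over the list alone and 9 with batch as a covariate. Hnf4a rose by 3.34 ± 0.49 (adjusted p = 0.00685), Sox17, a transcription factor of endoderm and endothelium, by 3.30 ± 0.65 and Apoc2 by 2.27 ± 0.46. The median was 2.04 (1.57 and 2.65 within the batches; adjusted p = 1.92e-09, but adjusted p = 0.350 with an estimated correlation). Of 20 endothelial genes 7 rose and 13 did not pass, while 17 rose when adjusted over the list alone and 12 with batch as a covariate. Flt1 and Flt4, receptors for vascular growth factors, rose by 2.99 ± 0.47 and 2.53 ± 0.35, and Sox18 by 2.72 ± 0.60. The median was 2.13 (1.82 and 2.48 within the batches; adjusted p = 3.87e-12, but adjusted p = 0.350 with an estimated correlation). The blood list went the other way with 0 of 16 called in limma, with Runx1 at -1.38 and Tal1 at -0.85. Its median was -1.02 (-0.65 and -1.20 within the batches; adjusted p = 0.00780, but adjusted p = 0.729 with an estimated correlation). Fibroblast and matrix genes also had 0 of 17 called, and 3 lower with batch as a covariate, among them Lum, a small matrix proteoglycan, at -3.45 (adjusted p = 0.0732, and 0.00595 with batch) and Dcn, decorin, at -2.69 (adjusted p = 0.126, and 0.0309 with batch). Their median of -1.11 came mostly from batch 1 (-2.15, against -0.19 in batch 2; adjusted p = 0.00311, but adjusted p = 0.623 with an estimated correlation). Both lists had 0 members past the threshold when adjusted over the list alone.

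Muscle genes at day 8 were higher in sum beside the endothelial and endodermal genes. Of 23 sarcomere genes 22 had positive differences, 0 passed in limma, 0 passed when adjusted over the list alone and 6 rose with batch as a covariate. Myl7 differed by 2.19 ± 0.72 (adjusted p = 0.126, and 0.0158 with batch) and Actn2 by 2.18 ± 0.76 (adjusted p = 0.150, and 0.0261 with batch). The median was 2.18 (1.67 and 2.53 within the batches; adjusted p = 4.65e-05, but adjusted p = 0.579 with an estimated correlation). Nkx2-5 differed by 1.78 ± 0.51 (adjusted p = 0.0846, and 0.0194 with batch) and Myh6 by 3.06 ± 1.63 (adjusted p = 0.336). Gata4, a transcription factor of heart and endoderm, rose by 1.91 ± 0.43 as 1 of 19 cardiac transcription factors, with 3 when adjusted over the list alone and 3 with batch as a covariate. That list's median was 0.84 (0.37 and 1.35 within the batches; adjusted p = 0.0290, but adjusted p = 0.674 with an estimated correlation). Calcium handling genes had 0 of 17 called, 5 higher when adjusted over the list alone and 2 higher with batch as a covariate, such as Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 2.04 (adjusted p = 0.106, and 0.00757 with batch). Their median was 0.97 (0.81 and 1.13 within the batches; adjusted p = 9.21e-04, but adjusted p = 0.350 with an estimated correlation). Mb rose by 2.25 ± 0.54 as 1 of 16 genes of natriuretic peptides and muscle energy metabolism, also 1 when adjusted over the list alone, with a median of 0.84 (0.81 and 0.86 within the batches; adjusted p = 0.00311, but adjusted p = 0.505 with an estimated correlation).

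Among other day 8 lists, Notch1 rose by 2.54 ± 0.34 (adjusted p = 0.00482) and Hey1 by 2.31 ± 0.41 as 2 of 19 cardiac signalling genes, with 3 when adjusted over the list alone. The signalling median was 0.51 (0.43 and 0.79 within the batches; adjusted p = 0.0431, but 0.0613 with batch as a covariate and adjusted p = 0.533 with an estimated correlation). Birc5 fell by 0.94 ± 0.15 as 1 of 23 cell cycle genes, with 2 lower when adjusted over the list alone and with batch as a covariate. The cell cycle median was -0.37 (-0.15 and -0.60 within the batches; adjusted p = 1.87e-06, but adjusted p = 0.505 with an estimated correlation). Klf4, a transcription factor of pluripotent cells and of endothelium, rose by 1.91 ± 0.31 as 1 of 19 pluripotency genes, a list that did not pass (adjusted p = 0.552). The lists of neuroectoderm, primitive streak, skeletal muscle, smooth muscle and dissociation stress did not pass, with adjusted p = 0.905, 0.599, 0.705, 0.343 and 0.466.

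**Figure D2:**
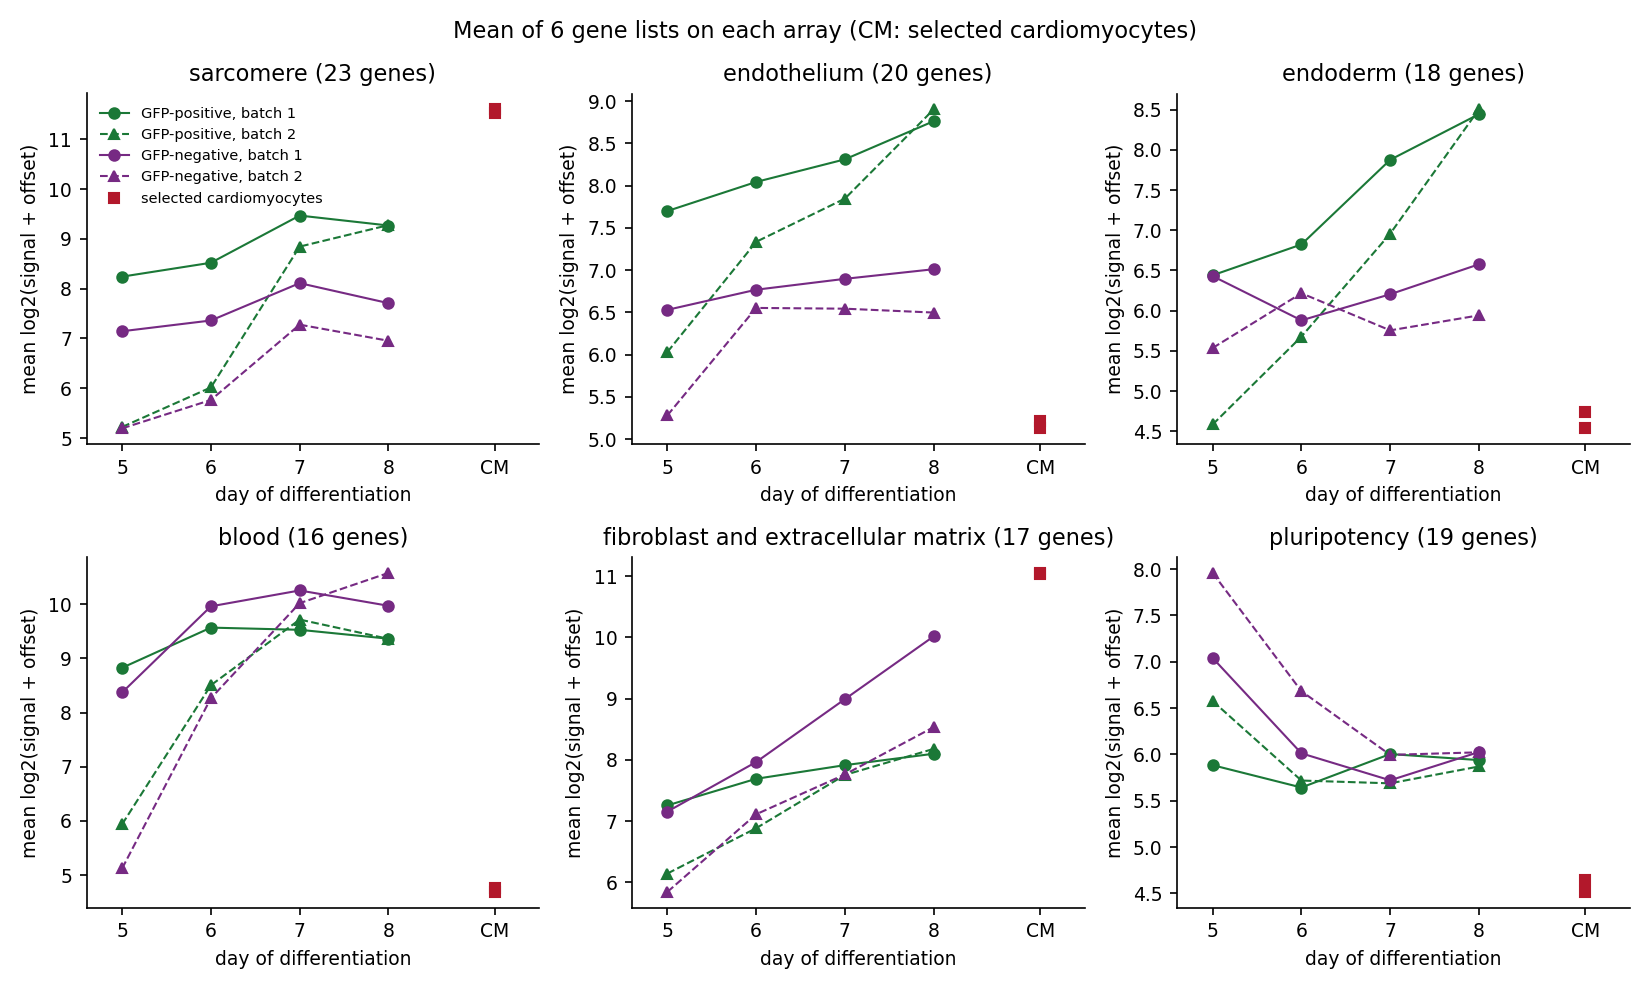
Mean log2(signal + 6.8) of the tested members of 6 gene lists on each array (sarcomere 23, endothelium 20, endoderm 18, blood 16, fibroblast and matrix 17, pluripotency 19 genes) by day of differentiation, fraction and batch, with the selected cardiomyocytes at the right. At day 8 the endothelial and endodermal means were higher in GFP-positive cells in both batches, with median differences of 2.13 and 2.04, while the blood list differed by -1.02.

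Day 8 was compared with day 5 within each fraction to follow differentiation. In GFP-positive cells the largest increases included genes of endoderm, the caveolar gene Cav1 and an embryonic globin. Igfbp1 rose by 7.92 ± 1.05 (log2; 2 arrays against 2; adjusted p = 0.00342), Nepn by 7.16 ± 1.05, Hbb-y, an embryonic beta-globin, by 6.68 ± 1.80, Cav1, the caveolar protein of endothelium and other cells, by 5.80 ± 0.80 and Apoa1, the main apolipoprotein of high-density lipoprotein, by 5.56 ± 1.07. Igfbp3 rose by 5.11, Sparcl1 by 5.08, Diras2 by 5.00, Ambp, a liver-secreted protein, by 4.76 and the chemokine Ccl9 by 4.68. The largest decreases were Fgf3 at -4.40 ± 0.81 and Fgf15 at -3.26 ± 0.48, both growth factors of the early embryo, Ms4a4d at -4.10, Snhg3 at -3.20, Phlda2 at -2.73 and Hoxb1 at -2.73. Etv2, the factor that starts blood and vessel development, fell by 2.63 ± 0.66, Gjb5 fell by 2.60, Bcat1 fell by 2.45 and the WNT agonist Rspo3 fell by 2.21. Nkx2-5 differed by 1.41 ± 0.51 (adjusted p = 0.0686, and 0.0167 with batch as a covariate; 0.53 in batch 1 and 2.29 in batch 2). Myh6 differed by 4.19 ± 1.63 (adjusted p = 0.0854, and 0.00590 with batch; 1.75 in batch 1 and 6.63 in batch 2).

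Of 18 endoderm genes 13 rose and 5 did not pass from day 5 to day 8 in GFP-positive cells, with 15 when adjusted over the list alone. Rbp4, the carrier of retinol, rose by 4.38 ± 1.03, Apob by 4.61 ± 0.94 and Fgb, a fibrinogen chain, by 3.24 ± 0.71. The median was 2.79 (1.99 and 3.40 within the batches; adjusted p = 1.74e-07, but adjusted p = 0.350 with an estimated correlation). Of 20 endothelial genes 12 rose and 8 did not pass, with 16 when adjusted over the list alone, such as Vwf, von Willebrand factor, by 3.57 ± 0.58, Emcn, endomucin, by 3.33 ± 0.79 and Tie1, an endothelial receptor, by 3.20 ± 0.88. Their median was 1.94 (0.99 and 3.09 within the batches; adjusted p = 6.10e-06, but adjusted p = 0.463 with an estimated correlation). Of 23 cell cycle genes 14 fell and 9 did not pass, with 18 when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell by 1.24 ± 0.21, Mcm2, part of the replicative helicase, fell by 1.15 ± 0.20 and Birc5 fell by 1.15 ± 0.15. Their median was -0.75 (-0.51 and -0.90 within the batches; adjusted p = 2.62e-10, but adjusted p = 0.350 with an estimated correlation).

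Lists of muscle genes passed in the same interval, with part of their members past the threshold. Of 23 sarcomere genes 3 rose and 20 did not pass, with 11 when adjusted over the list alone and 15 with batch as a covariate. Myom1, myomesin of the M-band, rose by 3.05 ± 0.85, Actn2 by 2.83 ± 0.76 and Tnni3, cardiac troponin I, by 2.40 ± 0.72. The median was 2.61 (0.99 and 4.04 within the batches; adjusted p = 3.37e-04, but adjusted p = 0.623 with an estimated correlation). Of 17 calcium handling genes 4 rose, Hrc by 2.39, Slc8a1 by 1.84, Pln, phospholamban, by 1.78 and Cacna1c by 1.47, with 7 when adjusted over the list alone and 7 with batch as a covariate. Their median was 1.12 (0.76 and 1.10 within the batches; adjusted p = 0.0367, but adjusted p = 0.547 with an estimated correlation). Of 16 genes of natriuretic peptides and muscle energy metabolism 7 rose and 9 did not pass, such as Lpl, lipoprotein lipase, by 2.81 ± 0.82, Mb by 2.26 ± 0.54 and the fatty acid carrier Cd36 by 2.13 ± 0.38, with 11 when adjusted over the list alone. Their median was 1.47 (0.99 and 2.08 within the batches; adjusted p = 8.86e-04, but adjusted p = 0.444 with an estimated correlation).

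Of 14 dissociation stress genes 8 rose and 1 fell in GFP-positive cells, the same counts as when adjusted over the list alone. Hspa1a, a heat shock protein, rose by 4.53 ± 0.94, Ier3 by 2.02 ± 0.32 and Zfp36, an immediate early gene, by 1.96 ± 0.37. The median was 0.98 (0.73 and 1.37 within the batches; adjusted p = 8.90e-04, but adjusted p = 0.350 with an estimated correlation). Of 17 fibroblast and matrix genes 3 rose, Col1a2, a chain of type I collagen, by 2.66 ± 0.86, Lox, a collagen crosslinking enzyme, by 2.40 ± 0.56 and Sparc, a matrix glycoprotein, by 1.57 ± 0.52. When adjusted over the list alone 6 rose and 1 fell, and 7 rose with batch as a covariate. Their median was 1.25 (0.75 and 1.67 within the batches; adjusted p = 0.0498, but adjusted p = 0.747 with an estimated correlation). Blood genes did not pass as a list (adjusted p = 0.189; median -0.04 in batch 1 and 2.88 in batch 2), while Hbb-y rose and Ptprc rose by 3.90 ± 0.99, the 2 that also rose when adjusted over the list alone.

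Single genes of the other lists also passed in GFP-positive cells. Among cardiac transcription factors Hand1 fell by 1.24 ± 0.39 and Srf, serum response factor, fell by 0.99 ± 0.20, and 5 rose with batch as a covariate (list adjusted p = 0.562). In cardiac signalling 3 rose and 2 fell: Hey1 rose by 1.36 and Notch1 by 1.15, and Bmp2 and Bmp4, bone morphogenetic proteins, fell, at -1.79 and -1.53 (list adjusted p = 0.456). Sox2 rose by 2.54 ± 0.60 and Gdf3 by 1.23 ± 0.30 while Dppa4, a nuclear protein of pluripotent cells, fell by 2.07 ± 0.53 among pluripotency genes (list adjusted p = 0.357). Pax6, an eye and neural transcription factor, rose by 2.06 and Tubb3, neuronal tubulin, fell by 2.06 (neuroectoderm list adjusted p = 0.653). Synpo2 and Mylk, myosin light chain kinase, rose by 2.28 and 1.24 (smooth muscle list adjusted p = 0.509). The primitive streak list had 0 of 16 called in limma, with Evx1 at -2.81 (adjusted p = 0.0783, and 0.0281 with batch as a covariate). The list had adjusted p = 0.0778, and 0.0415 with batch as a covariate, but with batch adjusted p = 0.659 with an estimated correlation (median 0.16 in batch 1 and -1.73 in batch 2). Skeletal muscle had 0 of 4 called (list adjusted p = 0.212).

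In GFP-positive cells 2579 genes differed between day 8 and day 5, 1477 higher and 1102 lower, and 1572 by at least 2-fold (1217 higher and 355 lower). The all-gene median moved with the scaling: it was 0.14 as deposited, -0.04 after quantile normalization and -0.37 with equal array medians, and the share of called genes that were higher was 57.3%, 46.5% and 14.9%. With equal array medians 4311 genes passed, 643 higher and 3668 lower, so the direction of small changes is relative to the scaling. No list that passed changed the sign of its median under either scaling in any comparison (0 and 0 lists). The count fell to 112 without the day 5 GFP-positive array of batch 2, 118 without day 8 GFP-positive batch 2 and 572 without day 8 GFP-positive batch 1. It was 82 without both day 5 arrays of batch 2, an alternative added after the data were seen.

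In GFP-negative cells the largest increases from day 5 to day 8 were in blood and matrix genes. Hbb-y rose by 7.34 ± 1.80 (log2; 2 arrays against 2; adjusted p = 0.0225), Col3a1, a chain of type III collagen, by 6.89 ± 1.67, Cx3cr1, a chemokine receptor of macrophages, by 6.65 ± 0.99, Clec1b, a platelet receptor, by 6.47 ± 1.22 and Pf4, platelet factor 4, by 6.39 ± 0.96. Slc4a1, the anion exchanger of red cells, rose by 6.38, the chemokines Ccl9 and Ccl6 by 6.26 and 6.11, Alas2, the heme synthesis enzyme of red cells, by 5.97 and Lum by 5.86. The largest decreases included genes of pluripotent and epiblast cells: Tdgf1, a Nodal coreceptor, fell by 4.46 ± 1.09, Eras, a stem cell Ras protein, fell by 4.46 ± 0.66 and Fgf5, a growth factor of the epiblast, fell by 4.32 ± 0.70. Slc27a2 fell by 3.92, Trh, thyrotropin-releasing hormone, fell by 3.89, Lhx1 fell by 3.89, Cyp26a1, a retinoic acid hydroxylase, fell by 3.76, Cer1, a secreted Nodal antagonist, fell by 3.71, Vrtn fell by 3.69 and Ms4a4d fell by 3.62. Nkx2-5 differed by 0.07 ± 0.51 (adjusted p = 0.947) and Myh6 by 1.95 ± 1.63 (adjusted p = 0.461; 1.28 in batch 1 and 2.63 in batch 2).

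Of 16 blood genes 9 rose and 7 did not pass, with 14 when adjusted over the list alone. Ptprc rose by 5.38 ± 0.99 and Rhag, a red cell membrane protein, by 4.92 ± 1.32. The median of 3.21 differed widely between batches (0.72 in batch 1 and 4.76 in batch 2; adjusted p = 4.95e-08, but adjusted p = 0.426 with an estimated correlation). Of 17 fibroblast and matrix genes 10 rose and 7 did not pass, with 13 higher and 1 lower when adjusted over the list alone, such as Postn, periostin, by 5.51 ± 1.35 and Col5a2 by 4.54 ± 0.81. Their median was 2.62 (2.63 and 2.25 within the batches; adjusted p = 8.03e-07, but adjusted p = 0.414 with an estimated correlation). Of 19 pluripotency genes 7 fell and 12 did not pass, with 9 when adjusted over the list alone. Pou5f1, which encodes Oct4, fell by 3.47 ± 0.97, Nanog fell by 3.21 ± 0.82 and Lin28a, an RNA-binding protein of stem cells, fell by 3.10 ± 0.42. Their median was -1.19 (-0.98 and -1.91 within the batches; adjusted p = 6.51e-05, but adjusted p = 0.350 with an estimated correlation). Of 16 primitive streak genes 3 fell, Lhx1, Gsc, goosecoid, at -2.01 and Nodal at -1.76, with 5 lower when adjusted over the list alone and 6 with batch as a covariate. Their median was -1.63 (-0.73 and -2.64 within the batches; adjusted p = 0.00126, but adjusted p = 0.584 with an estimated correlation).

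Further lists passed in GFP-negative cells with few members called. Of 10 neuroectoderm genes Otx2 fell by 2.80, Stmn2, a neuronal microtubule protein, fell by 2.75 and Sox3 fell by 1.32, the same 3 when adjusted over the list alone. Their median was -1.16 (-0.43 and -1.26 within the batches; adjusted p = 0.0355, but 0.0514 with batch as a covariate and adjusted p = 0.350 with an estimated correlation). Of 14 dissociation stress genes 3 rose, Zfp36 by 2.48, Egr1 by 1.21 and Btg2 by 1.12, with 6 when adjusted over the list alone and 5 with batch as a covariate. Their median was 0.72 (0.60 and 0.92 within the batches; adjusted p = 0.00111, but adjusted p = 0.350 with an estimated correlation). Of 19 cardiac signalling genes 5 fell, among them Dkk1, a WNT antagonist, at -1.83, Wnt5a at -1.59 and Bmp2 at -1.4, with 2 higher and 5 lower when adjusted over the list alone. Their median was -0.55 (-0.42 and -0.88 within the batches; adjusted p = 0.0433, but 0.0580 with batch as a covariate and adjusted p = 0.533 with an estimated correlation). Of 23 cell cycle genes Mcm3 fell by 0.82 and Rrm2 fell by 0.74, with 4 when adjusted over the list alone and 7 with batch as a covariate. Their median was -0.37 (-0.36 and -0.18 within the batches; adjusted p = 0.0181, but adjusted p = 0.741 with an estimated correlation). Of 20 endothelial genes Vwf alone rose, by 3.33 ± 0.58, also when adjusted over the list alone, and 2 rose with batch as a covariate. Their median was 0.92 (0.44 and 1.35 within the batches; adjusted p = 0.0477, but adjusted p = 0.741 with an estimated correlation).

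Sarcomere genes in GFP-negative cells had a median of 1.05 (0.45 and 1.56 within the batches), with adjusted p = 0.0510, and 0.00602 with batch as a covariate, but with batch adjusted p = 0.594 with an estimated correlation. Myom1 rose by 3.21 and Des, desmin, by 1.65, while 21 of 23 did not pass. The endoderm list did not pass (adjusted p = 0.956), and Cer1 and Foxa2, a transcription factor of endoderm and midline, fell, Foxa2 at -2.45. Mef2a rose by 1.20 and Srf fell by 0.72 (cardiac transcription factor list adjusted p = 0.951), and Gja1, the connexin 43 gene, fell by 1.45 (calcium handling list adjusted p = 0.468). Lpl rose by 4.34 and the glucose transporter gene Slc2a4 by 0.94 (energy metabolism list adjusted p = 0.325). Mylk rose by 1.63 (smooth muscle list adjusted p = 0.520) and Tnni2, the fast skeletal troponin I, by 2.87 (skeletal muscle list adjusted p = 0.582).

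In GFP-negative cells 1723 genes differed between day 8 and day 5, 977 higher and 746 lower, and 1123 by at least 2-fold (773 higher and 350.0 lower). The all-gene median was 0.00 as deposited and -0.22 with equal array medians, and the share of called genes that were higher was 56.7% as deposited, 49.0% after quantile normalization and 26.6% with equal array medians. The count was 30.0 without the day 5 GFP-negative array of batch 2, 544 without day 8 GFP-negative batch 2, 982 without day 8 GFP-negative batch 1, and 247 without both day 5 arrays of batch 2. Array weights lowered it to 821.

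The interaction asked whether the change from day 5 to day 8 differed between the fractions. H2-Bl, a class I histocompatibility gene of a family of similar sequences, was the 1 gene that passed in limma, against 1692 at an unadjusted p under 0.05. Its change was larger in GFP-positive cells by 4.36 ± 0.54 (log2; 2 arrays in each of 4 groups; adjusted p = 0.0282; 4.05 in batch 1 and 4.68 in batch 2). Its mean signal rose from 15.7 to 150.9 in GFP-positive cells and went from 57.4 to 15.3 in GFP-negative cells. With single arrays left out its adjusted p ranged from 0.0103 to 0.25 and missed the threshold in 4 of 8 fits, those without day 5 GFP-negative batch 2, day 8 GFP-negative batch 2 or either day 8 GFP-positive array. With batch as a covariate 137 genes passed (131 higher and 6 lower), among them Foxa2, at 4.58 ± 0.71 (adjusted p = 0.0517, and 0.0327 with batch), Hnf4a, at 3.70 ± 0.69 (adjusted p = 0.0541, and 0.0345 with batch) and Sox2, at 3.73 ± 0.85 (adjusted p = 0.0854, and 0.0327 with batch). The count was 57 without day 5 GFP-negative batch 1, 156 without day 5 GFP-positive batch 1 and 77 without day 8 GFP-negative batch 1. It was 0 without day 5 GFP-negative batch 2, day 8 GFP-negative batch 2 or day 8 GFP-positive batch 2, with 1281, 1119 and 1155 genes at an unadjusted p under 0.05.

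As lists, endoderm genes changed more in GFP-positive cells, with all 18 differences positive and 9 past the threshold when adjusted over the list alone. The median was 2.51 (2.05 and 3.32 within the batches; adjusted p = 2.01e-09, but adjusted p = 0.350 with an estimated correlation). Pluripotency genes had a median of 1.46 (1.5 and 1.21 within the batches; adjusted p = 9.44e-04, but adjusted p = 0.350 with an estimated correlation), with 5 past the threshold when adjusted over the list alone and Lefty1, a Nodal inhibitor, at 2.60. Endothelial genes had a median of 1.32 (0.59 and 1.71 within the batches; adjusted p = 0.00191, but adjusted p = 0.591 with an estimated correlation), with Flt1 at 2.83. Genes of natriuretic peptides and muscle energy metabolism had a median of 1.13 (0.79 and 1.25 within the batches; adjusted p = 0.0105, but adjusted p = 0.533 with an estimated correlation), with Cd36 at 2.01. In each of these last 2 lists 2 genes passed when adjusted over the list alone. Blood genes had a median of -1.6 (-1.25 and -1.97 within the batches; adjusted p = 2.84e-05, but adjusted p = 0.533 with an estimated correlation), with Runx1, a transcription factor of definitive blood, at -2.94 and 4 lower when adjusted over the list alone. Fibroblast and matrix genes had a median of -1.4 (-2.40 and -0.58 within the batches; adjusted p = 6.07e-04, but adjusted p = 0.550 with an estimated correlation), with Lum at -3.28 and 0 past the threshold when adjusted over the list alone. Cell cycle genes had a median of -0.48 (-0.24 and -0.66 within the batches; adjusted p = 1.14e-06, but adjusted p = 0.505 with an estimated correlation), with Birc5 at -1.01 (adjusted p = 0.0736, and 0.0422 with batch as a covariate), the 1 gene lower when adjusted over the list alone. Sarcomere genes had a median of 1.32 (0.48 and 1.90 within the batches), with adjusted p = 0.0581, and 0.00259 with batch as a covariate, but with batch adjusted p = 0.551 with an estimated correlation. Nkx2-5 differed by 1.35 ± 0.72 (adjusted p = 0.466) and Myh6 by 2.24 ± 2.30 (adjusted p = 0.734).

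The selected cardiomyocytes were set against day 8 GFP-positive cells. These groups differ in clone and selection, and the labels give the cardiomyocytes no day. The comparison uses the day 8 GFP-positive arrays used above, so it shares their chance values. Nppa, atrial natriuretic peptide, rose by 7.30 ± 0.37 (log2; 2 arrays against 2; adjusted p = 1.35e-07), from a mean signal of 34.5 to 6477. Ankrd1, a stress-responsive protein of the sarcomere, rose by 6.21 ± 0.35 and Myoz2, calsarcin of the Z-disc, by 6.08 ± 0.41. Several of the other largest increases were matrix or mesothelial genes: Cemip, a hyaluronan-degrading protein, rose by 6.94 ± 0.52, Serpinb1a, a protease inhibitor, by 6.80, Upk3b, a mesothelial membrane protein, by 6.56, Efemp1 and Fbln5, fibulins of the matrix, by 6.41 and 6.27, Aldh1a1, a retinaldehyde dehydrogenase, by 6.12 and Lox by 6.12. The largest decreases were in blood and endoderm genes. Hba-x, an embryonic alpha-globin, fell by 9.59 ± 2.45 (adjusted p = 0.00883), Hbb-y fell by 8.72, Igfbp1 fell by 8.5, Hbb-bh1 fell by 8.30, Ttr, transthyretin, fell by 8.09, Rbp4 fell by 7.73, Alas2 fell by 7.59, Nepn fell by 7.58, Apoa1 fell by 6.92 and Apob fell by 6.42. Nkx2-5 differed by 0.76 ± 0.51 (adjusted p = 0.270) and Myh6 by 1.66 ± 1.63 (adjusted p = 0.463). Myh6 signals were 8122.3 and 7891.5, against 2478.2 and 2592.9 in GFP-positive cells.

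Lists of endothelial, blood, endoderm and cell cycle genes were lower in the cardiomyocytes. Of 20 endothelial genes 18 fell and 2 did not pass, also 18 when adjusted over the list alone, with Sox18 at -5.68 ± 0.60, Plvap at -5.61 and Cldn5, a tight junction protein, at -5.30. The median was -3.84 (adjusted p = 5.64e-09, but adjusted p = 0.350 with an estimated correlation). Of 16 blood genes 14 fell, also 14 when adjusted over the list alone, and the median was -4.41 (adjusted p = 2.84e-05, but adjusted p = 0.533 with an estimated correlation). Of 18 endoderm genes 14 fell, also 14 when adjusted over the list alone, and the median was -3.54 (adjusted p = 1.81e-06, but adjusted p = 0.350 with an estimated correlation). Of 23 cell cycle genes 18 fell, and 20 when adjusted over the list alone, with Aurkb, a mitotic kinase, at -1.72 ± 0.22 and Birc5 at -1.70 ± 0.15. Their median was -1.19 (adjusted p = 1.22e-06, but adjusted p = 0.505 with an estimated correlation).

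Lists of contraction, calcium cycling, matrix and smooth muscle genes were higher in the cardiomyocytes. Of 23 sarcomere genes 7 rose and 16 did not pass, also 7 when adjusted over the list alone and 14 with batch as a covariate. Lmod2, an actin nucleator, rose by 4.65 ± 0.40, Actn2 by 4.08 ± 0.76 and Tnni3 by 3.84 ± 0.72. The median was 1.91 (adjusted p = 4.32e-06, but adjusted p = 0.533 with an estimated correlation). Of 17 calcium handling genes 11 rose, and 12 when adjusted over the list alone, with Trdn, triadin, rising by 5.08 ± 0.53, Pln by 4.90 ± 0.51, Casq2, cardiac calsequestrin, by 4.32 ± 0.33 and Sln, sarcolipin, by 3.74. Their median was 1.68 (adjusted p = 6.24e-08, but adjusted p = 0.350 with an estimated correlation). Of 16 genes of natriuretic peptides and muscle energy metabolism 11 rose, and 12 when adjusted over the list alone, with Nppb, brain natriuretic peptide, rising by 5.95 ± 0.57, Mb by 4.64 ± 0.54 and Pgam2, a muscle glycolytic enzyme, by 4.07. Their median was 1.56 (adjusted p = 4.27e-07, but adjusted p = 0.350 with an estimated correlation). Of 17 fibroblast and matrix genes 12 rose and 5 did not pass, also 12 when adjusted over the list alone, with Lox rising by 6.12 ± 0.56, Dcn by 5.67 ± 0.88 and Loxl1 by 4.10 ± 0.58. Their median was 3.0 (adjusted p = 7.99e-08, but adjusted p = 0.350 with an estimated correlation). Of 10 smooth muscle genes 7 rose, also 7 when adjusted over the list alone, with Actg2, smooth muscle gamma-actin, rising by 5.40 ± 0.44, Tagln by 3.61 and Myh11, smooth muscle myosin, by 2.59. Their median was 1.83 (adjusted p = 2.06e-05, but adjusted p = 0.350 with an estimated correlation).

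Of 19 cardiac transcription factors Tbx20, a factor of chamber development, rose by 2.81 ± 0.43, Hopx by 2.14 and Srf by 0.98, while Isl1, a factor of cardiac progenitors, fell by 2.54 ± 0.58, the same counts as when adjusted over the list alone and 5 higher and 2 lower with batch as a covariate. The list median was 0.75 (adjusted p = 0.0498, but adjusted p = 0.741 with an estimated correlation). In cardiac signalling 5 rose and 5 fell, with Hey1 at -3.90 ± 0.41 and Notch1 at -2.37 ± 0.34 (list adjusted p = 0.922). Of 19 pluripotency genes 6 fell, among them Lin28a at -5.52 ± 0.42 and Sox2 at -5.14 ± 0.60 (list adjusted p = 0.0758). Tubb3 rose by 5.11 ± 0.49 while Otx2 fell by 4.26 ± 0.66 among neuroectoderm genes (list adjusted p = 0.937). Of 14 dissociation stress genes 1 rose and 5 fell, with the immediate early genes Fos and Ier2 at -2.29 and -1.96 (list adjusted p = 0.351). Kdr fell by 4.59 and Nodal fell by 1.52 among primitive streak genes (list adjusted p = 0.466), and Acta1, skeletal alpha-actin, rose by 2.35 ± 0.80 as 1 of 4 skeletal muscle genes (list adjusted p = 0.620).

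**Figure D3:**
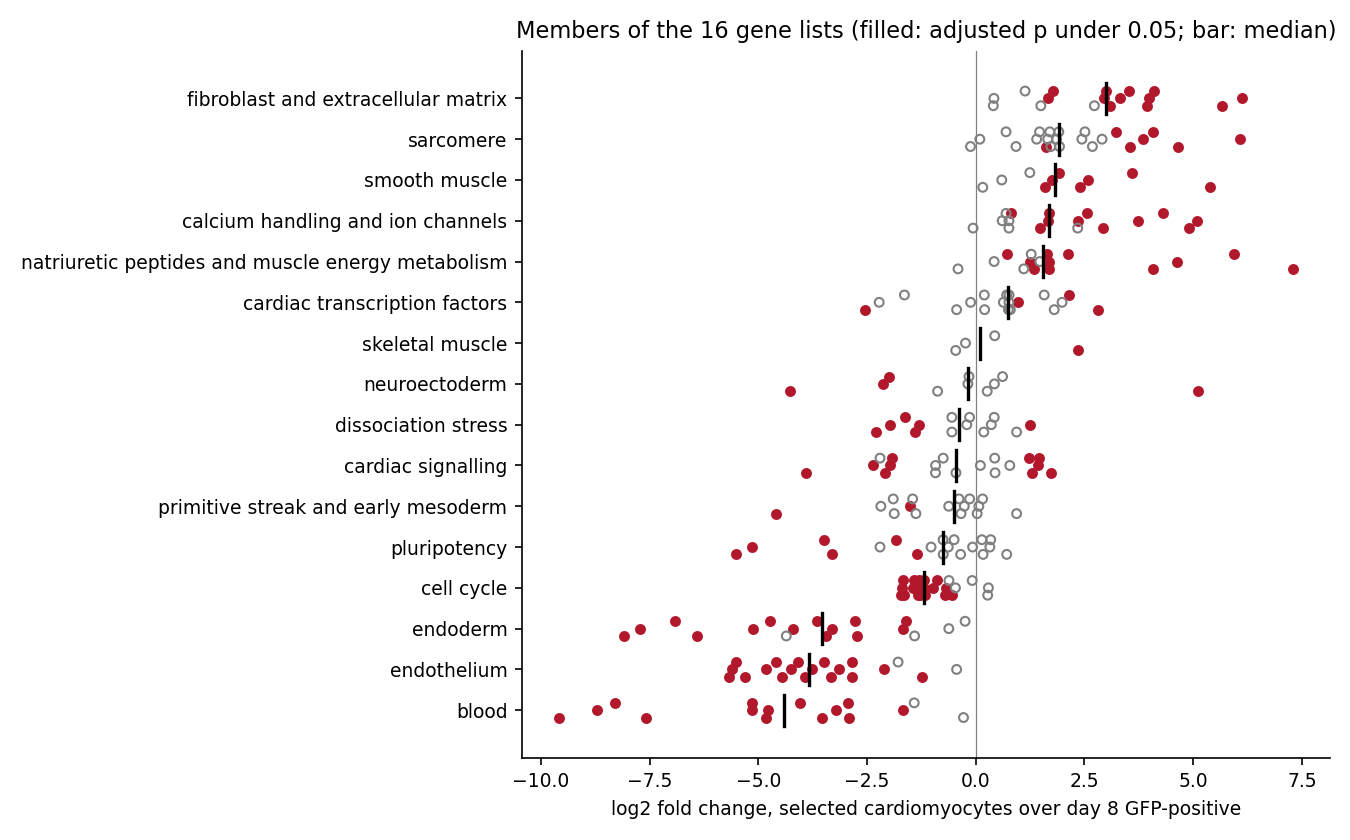
Log2 fold change of each tested gene of the 16 lists, selected cardiomyocytes over day 8 GFP-positive cells, with filled points for adjusted p under 0.05 and a bar at each list median. The endothelial, blood and endoderm medians were -3.84, -4.41 and -3.54, and the fibroblast and matrix median was 3.0.

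In all 4721 genes passed, 1809 higher and 2912 lower in the cardiomyocytes, and 3006 by at least 2-fold (1137 higher and 1869 lower). The all-gene median was -0.16 as deposited, 0.01 after quantile normalization and 0.33 with equal array medians, and the share of called genes that were higher was 38.3%, 46.6% and 75.6%. The count was 2912 without day 8 GFP-positive batch 2 and 2967 and 2845 without cardiomyocyte replicate 1 and 2.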

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

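In this part the tests of marker sets against blood, of the most abundant markers, and of the Gapdh ratio for endoderm were chosen after the result was seen. No group has 4 or more arrays, so arrays were not tested for lying far from their group.

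The change from day 5 to day 8 differed between the fractions by the interaction test for 1 gene and 7 lists. H2-Bl differed by 4.36 (log2). Blood genes differed by a median of -1.60, fibroblast and matrix genes by -1.40 and cell cycle genes by -0.48, so these rose less or fell more in GFP-positive cells. Median differences were 2.51 for endoderm, 1.46 for pluripotency, 1.32 for endothelium and 1.13 for natriuretic peptides and muscle energy metabolism. H2-Bl was not tested for cross-hybridization with similar sequences. Its call ended in 4 of 8 fits that left out 1 array. The list values passed with the preset correlation and 0 of 16 lists passed with an estimated correlation (camera in limma, 1 at an unadjusted p under 0.05).

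Endothelial and endodermal markers were higher in GFP-positive cells beside the genes of heart muscle. A lower share of one main cell type would raise the markers of all other types alike. Endothelial genes exceeded blood genes by 1.57 ± 1.17 (log2, mean and SD over 8 pairs; 7 of 8 pairs above 0; exact permutation p = 0.0156). This argues against a lower share of a type other than blood as the whole cause. A lower share of blood cells would give the same excess. For endoderm over all days the excess over blood was 1.06 ± 1.89 (5 of 8 pairs; exact permutation p = 0.164), so this cannot be told apart. On days 7 and 8, where the endoderm list passed, the excess was 2.54 ± 0.94 (4 of 4 pairs above 0; exact permutation p = 0.125, the smallest possible) and on days 5 and 6 it was -0.41 ± 1.29 (1 of 4 pairs above 0). At day 8 the blood list fell, at -1.02 (adjusted p = 0.00780, but adjusted p = 0.729 with an estimated correlation). So the marker sets moved apart by more than their spread on days 7 and 8. A lower share of blood cells would part them too, so this does not decide the cause. These days were picked after the result was seen, and 4 pairs cannot reach the threshold. The Gapdh ratio hardly differed between fractions (mean log2 0.020, 8 pairs; exact permutation p = 0.719). As a covariate it could shift little: medians of 1.47 (endothelium) and 1.12 (endoderm) leave RNA quality open. At day 8 the 10 most abundant markers of endothelium and the 10 of endoderm were all higher in GFP-positive cells of both batches. So were 9 of 10 other endothelial and 7 of 8 other endodermal markers. These counts follow from the list results and decide nothing. Endothelial and endodermal cells or transcripts in the sorted fraction, and enhancer activity in such cells, stay open.

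Chance is not excluded for the count of genes called by the sort, though few splits of the arrays called as many. Any split other than the sort leaves part of the difference between the fractions in the spread, which favours low counts. Among 100 of the 6435 splits of the 16 sorted arrays into 8 and 8, 2 called as many genes as the sort, the sort included: it called 185 in this fit and the highest other split called 271, while 97 called 0 genes in limma. The split with 271 put all 4 day 6 arrays on one side, with 1 of day 5, 1 of day 7 and 2 of day 8, of them 5 of the 8 GFP-positive arrays. The cause of its count was not tested. The split by batch called 1 gene. Among 100 of the 128 splits that exchanged fractions within pairs, 1 called as many, the sort itself, and the highest other called 82.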

How the results depend on the processing

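The alternatives without both day 5 arrays of batch 2, and batch as a covariate with an estimated correlation, were added after the data were seen. Unless stated, the cause was not tested.

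Counts of genes within 1.5 times of the reported value under every other alternative are not listed. For GFP-positive against GFP-negative cells over all days, 359 genes were reported and 728 passed with batch as a covariate and 595 with the day-and-batch pair as a block, which remove spread between batches by construction. On day 5, with 2 reported, the count was 0 with no offset, 12 with the offset at the median, 1 with quantile normalization, 1 without a filter, 5 without a variance trend and 4 with batch. It was also 0 with the filter at the 75th percentile, the mean of probe sets, every probe set on its own, array weights and the sorted arrays alone, with 441, 785, 1263, 493 and 721 at an unadjusted p under 0.05 in limma, and 796 with no offset. On day 6 it was 1 with batch, and on day 7 it was 1 with array weights. On day 8, with 347 reported, it was 178 with no offset, 529 with the offset at the median, 178 with equal array medians, 704 with batch and 185 with the sorted arrays alone.

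Between days 8 and 5 in GFP-positive cells, with 2579 reported, 4311 passed with equal array medians, 4094 with every probe set on its own, where more features are tested, and 82 without the day 5 arrays of batch 2. In GFP-negative cells, with 1723 reported, 821 passed with array weights and 247 without the day 5 arrays of batch 2. The interaction, with 1 reported, gave 80 with the offset at the median, 73 with quantile normalization, 25 with equal array medians, 62 with the mean of probe sets, 137 with batch and 120 with a linear trend. It gave 0 with no offset, the filter at the 75th percentile, array weights and the sorted arrays alone (1556, 1059, 1385 and 1512 unadjusted, limma). For the cardiomyocytes, with 4721 reported, 8383 passed with every probe set on its own.

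Leaving out 1 array at a time gave a range of 0 to 583 over all days, including each batch alone, 0 to 38 on day 5, 0 to 1 on day 6, 0 to 715 on day 8, 112 to 3043 and 30 to 1594 between days in GFP-positive and GFP-negative cells, 0 to 156 in the interaction and 2845 to 3248 for the cardiomyocytes; fewer samples widen the error by construction. On day 7 limma gave 0 in each of these fits, with 459 to 1341 unadjusted. Lists past the threshold were 70, and 0 with an estimated correlation (18 unadjusted) and 0 with batch as a covariate as well (28 unadjusted).

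Of the values of named genes with 1 array left out, 1 reversed, 1297 were the same, 53 became significant and 637 lost significance. Under other alternatives 3 reversed, 3629 were the same, 94 became significant and 339 lost significance. Myh7 in cardiomyocytes against day 8 GFP-positive cells turned to 0.41 with equal array medians and 2.03 with the mean of 4 GFP-positive groups as reference. Myh7 did not pass the threshold as reported or under these settings. Mixl1 between days in GFP-positive cells, which did not pass as reported, turned to 0.25 without the day 5 arrays of batch 2 and 0.25 without the GFP-positive one of these. Without the day 5 GFP-positive array of batch 1 Mixl1 was at -6.22 and passed (adjusted p = 0.00575). The call of H2-Bl ended with no offset, with array weights and with the sorted arrays alone, and the filter at the 75th percentile left H2-Bl out. Batch as a covariate changed the call of 9 lists, given in the report. With quantile normalization 3 list calls were lost: cell cycle and endothelium between days in GFP-negative cells and cardiac transcription factors in the cardiomyocytes (adjusted p = 0.0864, 0.0553 and 0.0891). It gained 3: calcium handling on day 5, and sarcomere between days in GFP-negative cells and in the interaction. Without the day 5 arrays of batch 2, 3 were lost: cell cycle and endothelium between days in GFP-negative cells, and fibroblast genes between days in GFP-positive cells (adjusted p = 0.144, 0.832 and 0.165), and 9 were gained.

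Signal over background limits depth: the median of all values was 22.5 units, and below it the offset of 6.8 units shrinks log2 changes.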

Other observations

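The lists of macrophage, platelet, epicardial, neural crest and Hox genes in this part, and all tests except that of the scaling, were chosen after the values were seen. These lists share Itga2b, Vwf and Pax3 with the lists of the report and hold genes named there, such as Wt1, Upk3b, Pf4 and Cx3cr1. Their p-values are therefore not tests of lists fixed beforehand.

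In GFP-negative cells macrophage genes rose from day 5 to day 8: 13 of 16 were called, with a median of 3.71 (log2; adjusted p = 4.36e-11, but adjusted p = 0.331 with an estimated correlation). Csf1r, the receptor for macrophage growth factor, rose by 5.58 ± 1.00 and Cd14, a coreceptor for endotoxin, by 5.28 ± 0.67. All 12 genes of megakaryocytes and platelets tested rose, with a median of 4.37 (adjusted p = 4.86e-12, but adjusted p = 0.331 with an estimated correlation), such as Tubb1, platelet tubulin, by 5.62 ± 0.83 and Gp9, part of the von Willebrand receptor, by 4.75 ± 0.61. In GFP-positive cells 11 macrophage and 11 platelet genes rose, with medians of 2.90 and 2.93 (adjusted p = 4.14e-05 and 1.03e-05, but adjusted p = 0.666 for both with an estimated correlation). The lists rose less in GFP-positive cells by the interaction test, with medians of -0.84 and -1.59 (adjusted p = 0.00305 and 0.00105). Both were lower in GFP-positive cells over all days, with medians of -0.66 and -0.76 (adjusted p = 1.34e-04 and 0.00374), on day 7 (-0.84 and -1.15; adjusted p = 0.00101 and 6.82e-04) and on day 8 (-1.13 and -1.39; adjusted p = 8.74e-05 and 9.44e-04). Each of these list results had adjusted p = 0.666 with an estimated correlation.

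In the selected cardiomyocytes 10 of 15 genes of epicardium and mesothelium rose over day 8 GFP-positive cells and 2 fell, with a median of 3.63 (adjusted p = 2.55e-05, but adjusted p = 0.331 with an estimated correlation). Tbx18, a factor of the epicardium, rose by 4.38 ± 0.45, Wt1 by 3.70 ± 0.46 and Msln, mesothelin, by 3.63 ± 0.46, while the keratin genes Krt8 and Krt18 fell, at -2.04 ± 0.25 and -2.01 ± 0.39. Of 12 platelet genes 9 fell there and 1 rose, with a median of -2.79 (adjusted p = 0.00418, but adjusted p = 0.666 with an estimated correlation). Of 14 neural crest genes 1 rose and 3 fell in the cardiomyocytes (list adjusted p = 0.841). Between the fractions on day 6 their median was -0.51 (adjusted p = 0.00194, but adjusted p = 0.331 with an estimated correlation). Hox genes gave 0 higher and 2 lower of 19 between the fractions over all days, with a median of -0.29 (adjusted p = 0.0325), and medians of -0.22 on day 7 and -0.54 on day 8 (adjusted p = 0.0286 and 0.0122; but in all of these adjusted p = 0.727 with an estimated correlation).

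Batch 2 arrays resembled earlier days than batch 1 arrays. On a score of 500 genes taken from batch 1 of the other fraction, the 8 batch 2 arrays lay 0.835 ± 0.580 days behind their day (mean and SD; 7 of 8 behind; exact permutation p = 0.0156), so slower differentiation in batch 2 may be a cause. A technical shift equal at every day is argued against, because the batch differences of fractions of the same day correlated across 13359 genes better than those of different days, by 0.233 (0.337 against 0.103; the highest of 24 matchings, exact one-sided p = 0.0417). This held on days 5, 6 and 7 (0.655, 0.400 and 0.339) and not on day 8 (-0.0467). With each gene's relation to the Gapdh ratio removed the lag was 1.07 days (8 of 8). Earlier versions of these tests decided nothing: the lag of early minus late days was 0.237 days (exact permutation p = 0.600), and genes that differed between batches numbered 278 before and 1149 with the ratio as a covariate. A difference in culture stays open.

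Matrix genes were higher in the selected cardiomyocytes than in day 8 GFP-positive cells. Scaling is argued against as the whole cause, since their median was 2.94 under quantile normalization (adjusted p = 6.79e-07, preset correlation). Of the 10 most abundant of these genes 10 were higher on both cardiomyocyte arrays, such as Sparc, Col3a1, Dcn and Lox, and so were 7 of 7 others, so this count follows from the list result and decides nothing. Selection with G418 for a gene under the Myh6 promoter is meant to remove other cells, and how far it did was not measured. Matrix-producing cells among the selected cells stay open. Clone, selection and time in culture were not tested apart from cell type.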
